A study of Homo sapiens with 21 samples.

How the data were processed

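The series asks, from its title, how asparagine starvation acts on histone methylation and gene expression. It holds 21 samples of RS4;11 cells kept for 24 h with asparagine, without it, or without it but with 10 µM ferric nitrate and 0.75 µM hinokitiol: 9 RNA libraries, 9 H3K4me3 ChIP libraries and 3 input libraries. Groups and replicate numbers were taken from the labels, and the columns called untreated in the peak table were read as complete medium.

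The RNA values are raw counts per gene that the authors deposited, made per the submitters' processing notes with bcl2fastq, STAR 2.7.2a and featureCounts of Subread 1.6.5 on hg38. The strand setting and the treatment of multi-mapping reads are not given in the sources used here, so counts of overlapping or antisense genes, such as FADS1 and FADS2, and of genes with close copies, such as H2AC6, are less certain. The table holds 66738 genes, of which 6180 lie on alternate contigs or are pseudoautosomal copies, and 2248 symbols are used more than once. Of the gene IDs, 60306 were found in the name table. The RNA libraries summed to 29362707 to 42478518 counts, and intervals given for low counts cover counting error only.

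The H3K4me3 values in the deposited table are of another kind: positions of the peaks called in each library, merged by the authors into 19279 regions, with no read counts, heights or p-values. Per the submitters' processing notes they were made with Bowtie2 2.4.4, Picard 2.18.26 and MACS2 2.2.7.1 on hg38. The peak threshold and the use of the inputs are not given in the sources used here. The table has 13 fields under 12 names, and the 4th field repeats the region in all 19279 lines, so the named library columns were read as the last 9 fields. Because the table holds positions alone, the planned test of peak counts could not be fitted. Gained and lost regions (called in 3 of 3 libraries of one group and 0 of 3 of the other) were counted instead, and a test of region widths was added after the data were seen. No reference genome was at hand, so no sequence was examined.

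The comparisons, tests, 33 gene lists with 923 members, and the rule for named genes were chosen before the data were examined, apart from the additions named as such. RNA was tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, also used for all CPM and for ratios of low counts, filterByExpr, robust quasi-likelihood fit over all 9 libraries, 3 contrasts), with Benjamini-Hochberg adjusted p under 0.05 called. The fit over 17939 genes had a biological coefficient of variation of 0.0871 and 6 residual degrees of freedom. Lists with at least 3 tested genes (32 of 33) were tested with camera of limma 3.58.1 at a preset correlation of 0.01, on log2 CPM with a prior count of 2. Widths, the covered length of a region in a library, were tested on the log2 scale with limma (trend) over 13883 regions called in all 9 libraries. Peak numbers were compared with an exact two-sided permutation test, promoter widths were set against RNA by Pearson's r and Spearman's rho with 100000 resamples and by two-sided Fisher's exact tests, and a promoter region lay within 1 kb of the outer 5' end of a gene. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1, numpy 2.4.6 and matplotlib 3.10.9 did the rest.

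Genes were named by a fixed rule. It took up to 8 genes per direction and contrast with the largest change among called genes with a mean of at least 5 CPM and groups that do not overlap (chance separates 10% of genes, 3 against 3), up to 3 called members of each list with a mean of at least 1 CPM, and 29 genes fixed in advance. It also took 5 regions per direction and contrast, and 151 genes were named. A gene with 1 to 3 counts in a group is given as a ratio with a 95% counting interval.

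Alternatives for RNA were DESeq2 1.42.0, RLE and upper-quartile factors, library totals only, no or a stricter low-count filter (at least 1 CPM in 3 libraries and a mean of 5), glmTreat against a 1.2-fold change, only the libraries compared, thinning to the smallest library, the replicate block and leaving out each library. For lists they were an estimated correlation, fry, library totals, the replicate block and leaving out each library. For regions and widths they were a minimum width, the 500 bp minimum, centring on the library median, outer spans, and for the promoter relation a 2 kb window, the nearest gene and summed peaks.

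The tests were tried on simulated data with 200 changed genes. With changes of 1.25-, 1.5-, 2- and 4-fold, 30%, 64%, 96% and 100% were recovered in -Asn vs +Asn, 24%, 74%, 96% and 100% in -Asn+Fe vs -Asn, and 30%, 68%, 92% and 100% in -Asn+Fe vs +Asn. Unchanged genes made up 8.23%, 8.13% and 7.64% of the calls, above the adjusted p threshold of 0.05. The real comparisons called 61.2%, 30.8% and 64.7% of 17939 genes, far more than the 200 changed here. These shares and the recovery need not carry over to them. Planted lists of genes raised 1.5- or 2-fold were called, and 0 of 32 random lists. Genes were drawn independently of each other here, so the list test was not tried on genes that vary together. Width changes of log2 0.25, 0.5 and 1 were recovered in 28.4%, 82.1% and 93.9% of regions in -Asn vs +Asn, in 35.8%, 71.6% and 93.9% in -Asn+Fe vs -Asn, and in 28.4%, 65.7% and 89.4% in -Asn+Fe vs +Asn. The input libraries have no values and were not analysed here.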

Results

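RS4;11, an established B-cell precursor acute lymphoblastic leukaemia line that carries a KMT2A-AFF1 fusion, was cultured for 24 h in 3 media: complete medium (+Asn), asparagine-free medium (-Asn), and asparagine-free medium with 10 µM ferric nitrate and 0.75 µM hinokitiol, a small molecule that carries iron across membranes (-Asn+Fe). Whole-cell RNA was sequenced in 3 libraries per medium. H3K4me3, a histone mark of active promoters, was profiled by ChIP-seq in 3 libraries per medium, with 1 input library per medium that has no values of its own here. The RNA libraries summed to between 39155120 and 40988303 counts in +Asn, 36773377 and 41898475 in -Asn, and 29362707 and 42478518 in -Asn+Fe. The ± values are SDs over the 3 libraries of a group (n = 3) throughout, and CPM is the count scaled to the library total times its TMM factor, a scaling for composition that lay between 0.888 and 0.912 in +Asn, 1.02 and 1.06 in -Asn, and 1.06 and 1.09 in -Asn+Fe. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

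The first comparison asks what RS4;11 cells did after 24 h without asparagine. RNAs of the amino acid response rose. DDIT3, a transcription factor of the integrated stress response, rose 26.7-fold, from 6.38 ± 0.215 to 170.2 ± 28.8 CPM, and CHAC1, an enzyme that breaks down glutathione, rose 42.5-fold, from 0.819 ± 0.275 to 35.2 ± 4.29 CPM. TRIB3, a pseudokinase of the same response, rose 43.2-fold to 214 ± 11.2 CPM. ATF4, the transcription factor at the centre of this response, rose 2.03-fold (log2 1.02 with SE 0.0905), from 430.1 ± 8.36 to 871 ± 126 CPM. SLC7A11, the cystine transporter (ENSG00000151012.13, chromosome 4, 138164097 to 138242349 of hg38), rose 14.7-fold, from 17.4 ± 1.59 to 256 ± 68.8 CPM.

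Of 33 tested members of the fixed list of ATF4 and amino acid response genes, 30 rose and 0 fell, with a median log2 fold change of 1.72 (camera adjusted p = 1.14e-13, and adjusted p = 0.0147 with an estimated correlation). Members that rose also included VEGFA, the vascular growth factor (log2 4.75), ATF3 (log2 4.17) and INHBE (log2 8.91, from 0.0746 ± 0.0183 to 37.3 ± 1.29 CPM). ASNS, which encodes asparagine synthetase, was near the detection limit in every medium, at 0.332 ± 0.143 CPM in +Asn and 0.352 ± 0.0365 CPM in -Asn (log2 0.08, adjusted p = 0.878). SESN2, also on the list, was at 0.0375 ± 0.0174 and 0.145 ± 0.0850 CPM and was too low to be tested. Among cytosolic aminoacyl-tRNA synthetases 11 rose and 7 fell of 19 (camera adjusted p = 0.121), and WARS1, for tryptophan, rose 20.3-fold to 1978 ± 83.0 CPM. SARS1 and AARS1 rose by log2 1.85 and 1.51. In serine, glycine and one-carbon synthesis 9 rose and 6 fell of 16 (camera adjusted p = 0.554). The serine pathway enzymes PSAT1, SHMT2 and PHGDH rose (log2 1.56, 1.58 and 0.71).

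Genes of DNA replication fell together. All 39 tested S phase and E2F target genes were lower in -Asn, with a median log2 fold change of -1.70 (camera adjusted p = 1.15e-20, and adjusted p = 0.0936 with an estimated correlation). CCNE2, a cyclin of the entry into S phase, fell from 184 ± 4.68 to 18.9 ± 2.42 CPM, and MCM4, a subunit of the replicative helicase, from 899 ± 16.1 to 128 ± 2.50 CPM. RRM1, a subunit of ribonucleotide reductase, fell (log2 -2.85), and UNG, a uracil-DNA glycosylase, and CCNE1 both fell (log2 -3.31 and -3.31). Of 36 G2 and mitosis genes 27 fell and 4 rose (median log2 -0.62, camera adjusted p = 3.07e-05, and adjusted p = 0.169 with an estimated correlation). CCNA2 and KIF20A, a cyclin and a mitotic kinesin, fell (log2 -1.44 and -1.46).

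Ribosome biogenesis and MYC target genes also fell, 29 of 34 with 0 higher (median log2 -0.61, camera adjusted p = 2.58e-08, and adjusted p = 0.0936 with an estimated correlation). UBTF, a factor of RNA polymerase I, fell (log2 -1.72), and MYC itself from 378 ± 9.60 to 264 ± 21.4 CPM. In cholesterol synthesis and uptake 21 of 23 genes fell and 1 rose (median log2 -1.01, camera adjusted p = 2.20e-08, and adjusted p = 0.0147 with an estimated correlation). The sterol enzymes DHCR7 and HMGCS1 fell (log2 -1.96 and -1.60). In fatty acid synthesis 11 of 13 fell, among them SCD, the stearoyl-CoA desaturase (log2 -2.09), and FADS2 (log2 -1.83), which overlaps FADS1 in the genome. That list had a median log2 of -0.88 (camera adjusted p = 6.34e-05, and adjusted p = 0.0936 with an estimated correlation). Heat shock response genes fell in 10 of 12 cases (median log2 -1.42, camera adjusted p = 5.06e-05, and adjusted p = 0.169 with an estimated correlation). The chaperone HSPH1 fell from 559 ± 27.5 to 131 ± 6.80 CPM and HSPA8 from 1541 ± 54.9 to 446 ± 44.6 CPM.

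Stress and death genes rose in part. Of 23 p53 targets 15 rose and 4 fell (median log2 0.58, camera adjusted p = 0.000820, and adjusted p = 0.169 with an estimated correlation). TNFRSF10B, a death receptor for TRAIL, rose 25.9-fold to 131 ± 5.64 CPM and CDKN1A, the cyclin-dependent kinase inhibitor p21, from 60.7 ± 8.79 to 190.4 ± 13.2 CPM. BBC3 (PUMA) and GADD45A rose by log2 2.32 and 2.30. Apoptosis regulators went both ways, with 13 up and 8 down of 22 (camera adjusted p = 0.286): PMAIP1 (NOXA) rose and BID fell (log2 1.41 and -1.81). Among endoplasmic reticulum chaperones and unfolded protein response genes 13 rose and 3 fell of 23 (median log2 0.67, camera adjusted p = 0.00212, and adjusted p = 0.169 with an estimated correlation). ERN1, which encodes the sensor IRE1, rose 20.1-fold and HERPUD1 5.16-fold. In autophagy and lysosome 16 rose and 6 fell of 36 (camera adjusted p = 0.134), with MAP1LC3B, an autophagosome protein, at 96.3 ± 4.63 CPM in +Asn and 461 ± 17.2 CPM in -Asn.

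Iron genes moved apart. TFRC, the transferrin receptor that brings iron into cells (ENSG00000072274.13, chromosome 3, 196027183 to 196082096), fell from 599 ± 14.7 to 106 ± 9.55 CPM (log2 -2.49 with SE 0.0779). FTH1, the heavy chain of the iron store ferritin (ENSG00000167996.16, chromosome 11, 61959718 to 61967634), rose from 340.1 ± 8.78 to 786 ± 146 CPM (log2 1.21 with SE 0.102). The light chain FTL was at 378 ± 13.1 and 442 ± 71.2 CPM (log2 0.23, adjusted p = 0.0452), a call that did not pass with DESeq2, RLE factors, or the 1.2-fold minimum, nor with any single +Asn or -Asn+Fe library, or -Asn replicate 1, left out. ACO1, an iron-responsive aconitase, and STEAP3, an iron reductase, fell (log2 -1.41 and -1.61), and the iron exporter SLC40A1 was at 0.540 ± 0.0895 and 0.393 ± 0.0881 CPM. The iron handling list held 6 higher and 9 lower genes of 20 (camera adjusted p = 0.217), and heme and iron-sulfur cluster synthesis held 7 and 12 of 29 (camera adjusted p = 0.248). ALAD and CPOX, of heme synthesis, fell (log2 -1.02 and -1.13).

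Histone demethylases of the JmjC family, which need iron and 2-oxoglutarate, went both ways, with 10 up and 7 down of 22 (median log2 0.23, camera adjusted p = 0.213). KDM6B, an H3K27 demethylase, rose 7.16-fold from 35.2 ± 0.893 to 252 ± 4.02 CPM, and KDM5B, an H3K4 demethylase, 12.9-fold from 0.896 ± 0.164 to 11.7 ± 0.611 CPM. KDM4A and KDM4B rose by log2 0.99 and 1.15, and KDM5C and KDM6A by 0.49 and 0.48. KDM5A (log2 0.22) and KDM4C (log2 0.10) did not pass the test. Of 22 genes of H3K4 methyltransferase complexes 12 fell and 2 rose (median log2 -0.35, camera adjusted p = 0.00684, and adjusted p = 0.245 with an estimated correlation). KMT2A fell from 554 ± 39.0 to 356 ± 65.5 CPM, and SETD1A, PAXIP1 and HCFC1 also fell (log2 -0.56, -1.27 and -1.08). The other iron and oxoglutarate dioxygenases held 6 higher and 5 lower genes of 23 (camera adjusted p = 0.889).

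Markers of the B lineage fell in part. Of 29 precursor B cell markers 21 fell and 7 rose (median log2 -0.73, camera adjusted p = 0.000820, and adjusted p = 0.0936 with an estimated correlation). IGLL1, a chain of the surrogate light chain, fell from 281 ± 27.0 to 66.8 ± 8.16 CPM and RAG2, of the V(D)J recombinase, from 57.5 ± 2.26 to 14.8 ± 1.65 CPM, and FCRLA rose (log2 2.56). KMT2A fusion targets held 10 higher and 5 lower genes of 25 (camera adjusted p = 0.230), with HOXA9 at log2 0.50, LMO2 at 1.31 and MEIS1 at 0.14 (adjusted p = 0.0795). Oxidative phosphorylation genes fell in 32 of 58 cases and rose in 5 (median log2 -0.36, camera adjusted p = 0.000820, and adjusted p = 0.634 with an estimated correlation). Mitochondrially encoded mRNAs fell in 11 of 13 (median log2 -0.44, camera adjusted p = 0.0111, and adjusted p = 0.573 with an estimated correlation), and mitochondrial genes took 6.67 ± 0.827%, 6.05 ± 0.667% and 5.33 ± 0.168% of the counts in +Asn, -Asn and -Asn+Fe.

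Among the other fixed lists, mitochondrial aminoacyl-tRNA synthetases held 4 up and 9 down of 15 (camera adjusted p = 0.239), NRF2 targets 6 up and 10 down of 18 (adjusted p = 0.267) and hypoxia-inducible factor targets 10 up and 13 down of 29 (adjusted p = 0.554). Metallothioneins and zinc export held 0 up and 3 down of 6 (adjusted p = 0.239), cytosolic ribosomal proteins 33 up and 5 down of 77 (adjusted p = 0.0867) and interferon-stimulated genes 9 up and 10 down of 25 (adjusted p = 0.913). For the NRF2, hypoxia and interferon lists the median, mean and camera direction differed in sign. Adjusted over the list alone, the counts in -Asn vs +Asn stayed as given except in the lists that follow: 0 higher and 30 lower in ribosome biogenesis, 1 and 11 in fatty acid synthesis, 11 and 7 in the JmjC list, 18 and 1 in replication-dependent histones, 5 and 9 in mitochondrial aminoacyl-tRNA synthetases, 8 and 12 in heme synthesis, 7 and 10 in NRF2 targets and 30 and 5 in ribosomal proteins.

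Genes outside the lists included some with almost no RNA in complete medium. CNTN4, a neural cell adhesion gene, had 1 count over the 3 +Asn libraries and 1705 over the 3 -Asn libraries, a ratio on the CPM scale of 1512 with a 95% counting interval of 271 to 59758. JMY had 1 and 860 counts (ratio 763, interval 137 to 30159), and GDF15, a stress cytokine, 1 and 715 (ratio 634, interval 113 to 25080). KLHDC7B, GDAP1L1, ESRP1 and the homeobox gene DLX2 rose to 28.8, 17.9, 10.8 and 14.1 CPM (log2 9.18, 8.24, 8.07 and 7.51). They had 5, 6, 4 and 8 counts over the 3 +Asn libraries, and over 19 other settings these log2 values ranged from 8.61 to 10.68, 7.66 to 9.99, 7.504 to 9.30 and 6.95 to 7.89. CTDSPL, MEGF10, DRAXIN and ITPRIPL1 fell (log2 -3.29, -3.25, -3.13 and -3.11).

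**Figure D1:**
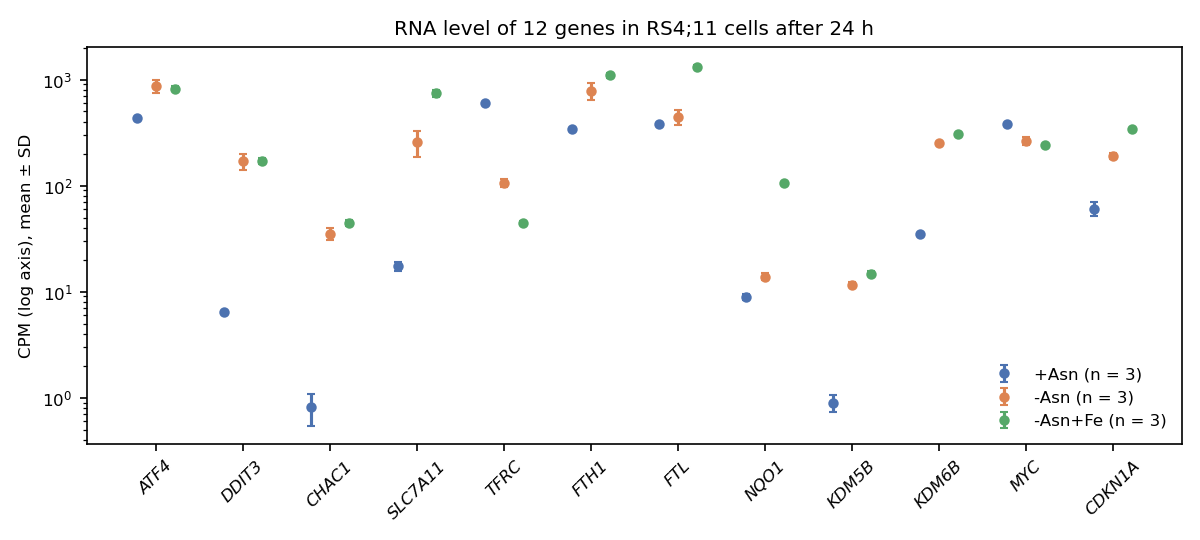
RNA level in CPM (log axis) of 12 genes in +Asn, -Asn and -Asn+Fe, as points for the mean and bars for the SD of 3 libraries. TFRC was at 599, 106 and 44.3 CPM in the 3 media, and NQO1 at 8.89, 13.9 and 105 CPM.

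The quasi-likelihood test of edgeR over 17939 genes called 10971 genes (61.2%) between -Asn and +Asn, 5558 higher and 5413 lower, at a Benjamini-Hochberg adjusted p below 0.05. Of these, 2616 rose and 1481 fell at least 2-fold, and the -Asn and +Asn libraries lay apart on a first principal component that took 70.3% of the variance. The count test gives changes relative to the bulk of genes: with library totals only, the median gene moved up by 0.21 and the calls became 7343 higher and 3836 lower, and with upper-quartile factors by 0.16 and 6904 and 4222. The stricter low-count filter moved the median by 0.12. Replicate 1 of -Asn stood apart from its group: the chi-square per degree of freedom was 37.0 and 40.8 in its pairs and 5.73 between -Asn replicates 2 and 3. Without it 11170 genes were called.

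The next comparison asks what added iron did to asparagine-starved cells. HMOX1, NQO1 and the ferritin genes FTL and FTH1 were among the genes that rose. HMOX1, the heme oxygenase that frees iron from heme (ENSG00000100292.17, chromosome 22, 35380361 to 35394207), rose 96.3-fold, from 0.142 ± 0.0475 CPM in -Asn to 13.8 ± 2.28 CPM in -Asn+Fe, or from 17 to 1527 counts over 3 libraries each. NQO1, a quinone reductase, rose from 13.9 ± 0.997 to 105 ± 3.08 CPM and FTL from 442 ± 71.2 to 1323 ± 47.8 CPM. GCLM, of glutathione synthesis, rose from 32.6 ± 3.14 to 134 ± 5.82 CPM, SLC7A11 from 256 ± 68.8 to 742 ± 61.2 CPM and FTH1 from 786 ± 146 to 1099 ± 57.2 CPM. Of 18 NRF2 targets 16 rose and 0 fell, with a median log2 fold change of 0.90 (camera adjusted p = 1.62e-13, and adjusted p = 0.0182 with an estimated correlation).

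TFRC fell again with iron, from 106 ± 9.55 to 44.3 ± 2.11 CPM (log2 -1.26 with SE 0.0766). The iron handling list held 6 higher and 4 lower genes of 20 (camera adjusted p = 0.262). OSGIN1, an oxidative stress gene, LUCAT1, a long noncoding RNA, COL24A1 and BIRC3, an inhibitor of apoptosis, rose by log2 3.09, 3.04, 3.20 and 2.81. The noncoding RNA PURPL and the kinase gene DGKG rose by 2.82 and 2.53. Heat shock genes, lower without asparagine, rose in 9 of 12 cases (median log2 0.49, camera adjusted p = 1.08e-06, and adjusted p = 0.140 with an estimated correlation). HSPH1 went from 131 to 294 ± 11.7 CPM and HSPA8 from 446 to 852 ± 26.1 CPM, both still below +Asn (log2 -0.93 and -0.85).

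Cell-cycle genes fell with iron. All 39 S phase genes and all 36 G2 and mitosis genes were lower than in -Asn, with median log2 fold changes of -0.95 and -1.03 (camera adjusted p = 8.22e-30 and 4.55e-27, and adjusted p = 0.0545 and 0.0182 with an estimated correlation). TK1, thymidine kinase, went from 96.0 ± 10.3 CPM in +Asn to 22.8 ± 2.63 in -Asn and 5.54 ± 0.298 in -Asn+Fe. E2F8, a repressor of the E2F family, was at 166 ± 9.29, 91.8 ± 3.37 and 17.6 ± 1.07 CPM. PAQR4 and SPC24, a kinetochore protein, fell (log2 -2.31 and -2.27), as did FAM111B, ARHGEF39 and IQGAP3 (log2 -2.04, -2.09 and -2.08). In -Asn vs +Asn, by contrast, IQGAP3 had risen (log2 0.93), ARHGEF39 had not passed the test (log2 -0.17), and 4 of the 36 G2 and mitosis genes had risen. Of 23 p53 targets 17 rose and 0 fell (median log2 0.53, camera adjusted p = 7.16e-08, and adjusted p = 0.0545 with an estimated correlation), with CDKN1A going from 190.4 to 338 ± 14.3 CPM and GADD45A from 76.1 to 128 ± 4.28 CPM.

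ATF4 and amino acid response genes stayed high with iron: 13 of 33 rose and 1 fell against -Asn (median log2 0.17, camera adjusted p = 0.00956, and adjusted p = 0.140 with an estimated correlation). DDIT3 was at 170.4 ± 10.2 CPM and ATF4 at 819 ± 44.9 CPM, neither passing the test against -Asn (adjusted p = 0.994 and 0.485). KDM6B rose to 309 ± 7.70 CPM (log2 0.29) and KDM5B to 14.7 ± 0.788 CPM (log2 0.34). Both calls were lost with a 1.2-fold minimum, and the KDM5B call without -Asn replicate 2, -Asn+Fe replicate 1 or -Asn+Fe replicate 3. The JmjC list held 7 up and 2 down of 22 (camera adjusted p = 0.231), the H3K4 methyltransferase list 1 up and 6 down of 22 (adjusted p = 0.413), and KMT2A was at 386 ± 6.21 CPM.

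Other lists moved with iron too. Oxidative phosphorylation genes fell in 27 of 58 cases (median log2 -0.28, camera adjusted p = 7.42e-05, and adjusted p = 0.646 with an estimated correlation). Heme and iron-sulfur cluster synthesis held 2 up and 12 down of 29, mitochondrial aminoacyl-tRNA synthetases 0 up and 8 down of 15, and metallothioneins 0 up and 3 down of 6 (camera adjusted p = 0.00642, 0.00956 and 0.0216, and adjusted p = 0.425, 0.165 and 0.3003 with an estimated correlation). Interferon-stimulated genes held 11 up and 1 down of 25, apoptosis regulators 9 up and 0 down of 22, and autophagy and lysosome genes 14 up and 3 down of 36 (camera adjusted p = 0.00106, 0.00642 and 0.00981, and adjusted p = 0.0545, 0.140 and 0.309 with an estimated correlation). Unfolded protein response genes held 8 up and 1 down of 23, hypoxia-inducible factor targets 7 up and 4 down of 29, and precursor B cell markers 3 up and 13 down of 29 (camera adjusted p = 0.00981, 0.0216 and 0.00981, and adjusted p = 0.206, 0.140 and 0.140 with an estimated correlation). KMT2A fusion targets held 8 up and 2 down of 25 and cytosolic ribosomal proteins 0 up and 5 down of 77 (camera adjusted p = 0.0276 and 0.00981, and adjusted p = 0.562 and 0.723 with an estimated correlation). Without -Asn replicate 1 the camera adjusted p of these last lists became 0.0843 and 0.875, and the ribosomal list gave 0.0706 without -Asn+Fe replicate 1 and 0.0517 without -Asn+Fe replicate 3. The hypoxia list gave 0.0511 without -Asn+Fe replicate 2, and with fry the ribosomal, KMT2A and oxidative phosphorylation lists gave 0.337, 0.0566 and 0.0829. Adjusted over the list alone, the counts in -Asn+Fe vs -Asn stayed the same except in the lists that follow, given as higher and lower: 18 and 0 for NRF2 targets, 18 and 0 for p53 targets, 11 and 0 for heat shock, 14 and 3 for ATF4 genes, 12 and 1 for interferon-stimulated genes and 9 and 1 for the unfolded protein response. They were 0 and 31 for oxidative phosphorylation, 2 and 14 for heme synthesis, 2 and 8 for mitochondrial and 3 and 7 for cytosolic aminoacyl-tRNA synthetases, 3 and 8 for serine and glycine synthesis, 0 and 4 for metallothioneins and 3 and 16 for precursor B cell markers. They were 0 and 0 for ribosomal proteins, 2 and 6 for mitochondrial mRNAs, 4 and 5 for fatty acid synthesis, 8 and 5 for iron handling, 8 and 2 for the JmjC list, 8 and 4 for hypoxia-inducible factor targets, 9 and 2 for KMT2A fusion targets and 1 and 2 for fibroblast and epithelial markers.

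The test called 5525 genes between -Asn+Fe and -Asn, 2506 higher and 3019 lower, of which 597 rose and 350 fell at least 2-fold. Against a 1.2-fold minimum (glmTreat) 2323 genes passed, and with upper-quartile factors the calls became 3196 higher and 2419 lower, and with library totals only 3023 and 2487. Replicate 2 of -Asn+Fe lay farthest from the mean of the others in its group of all 9 libraries (root mean square log2 deviation 0.483, against 0.421 for -Asn replicate 1) and apart from them on the third principal component (40.2 against -22.1 and -20.8). Without it 4985 genes were called here and 11337 between -Asn+Fe and +Asn. In these libraries iron came with hinokitiol, so the values belong to the pair of additions.

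**Figure D2:**
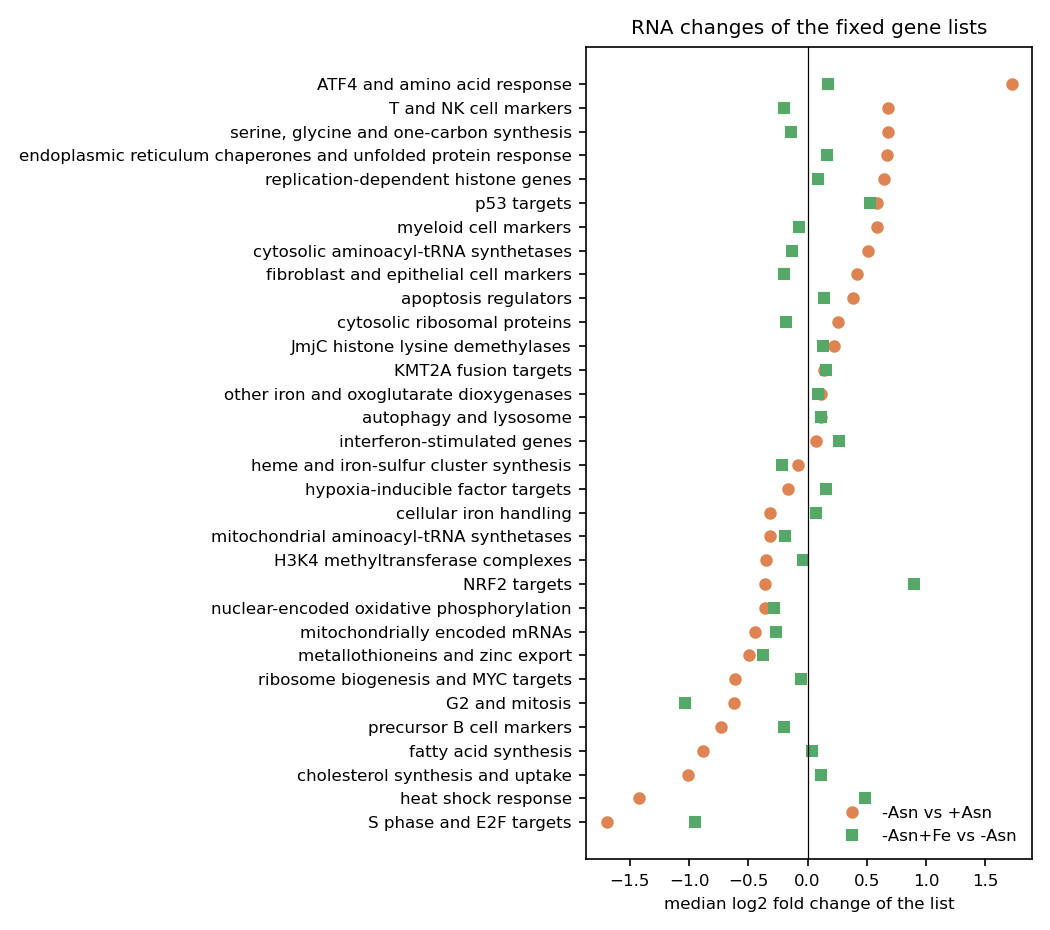
Median log2 fold change of each fixed gene list with at least 3 tested genes, in -Asn vs +Asn (circles) and in -Asn+Fe vs -Asn (squares). The S phase list lies at -1.70 and -0.95, the NRF2 list at -0.36 and 0.90, and the ATF4 list at 1.72 and 0.17.

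Whether iron brought the RNA changes of asparagine starvation back was read gene by gene. Of the 10971 genes changed without asparagine, 1863 (16.98%) moved the opposite way with iron and 2099 (19.1%) moved on in the same direction. Independent lists of these lengths would share 1691.5 and 1687.4 genes. The -Asn libraries enter both comparisons with opposite sign, so their noise favours opposite changes and independent lists are no exact gauge. Genes that moved the opposite way included HSPH1, HSPA8, RAG2 and INHBE (log2 -0.62 with iron), and genes that moved on included SLC7A11, TFRC, TK1 and CDKN1A. An opposite move was not a full return. Over 19 other settings, INHBE stayed above +Asn by log2 8.11 to 8.54, and RAG2 stayed at -1.35 to -1.06. In -Asn+Fe, 9059 of the 10971 genes (82.6%) still differed from +Asn, and 880 of the 1863 opposite genes did not. Both comparisons with +Asn use the same +Asn libraries, so part of this overlap can come from them. Across genes, the covariance of both log2 fold changes was 0.0396, against -0.0324 in simulated groups with no effect that share the -Asn libraries, a difference of 0.0720. The correlation was 0.0646 against -0.489 in the simulations. The simulated log2 fold changes vary by noise alone, without the large -Asn effect, so these correlations are not on the same scale.

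**Figure D3:**
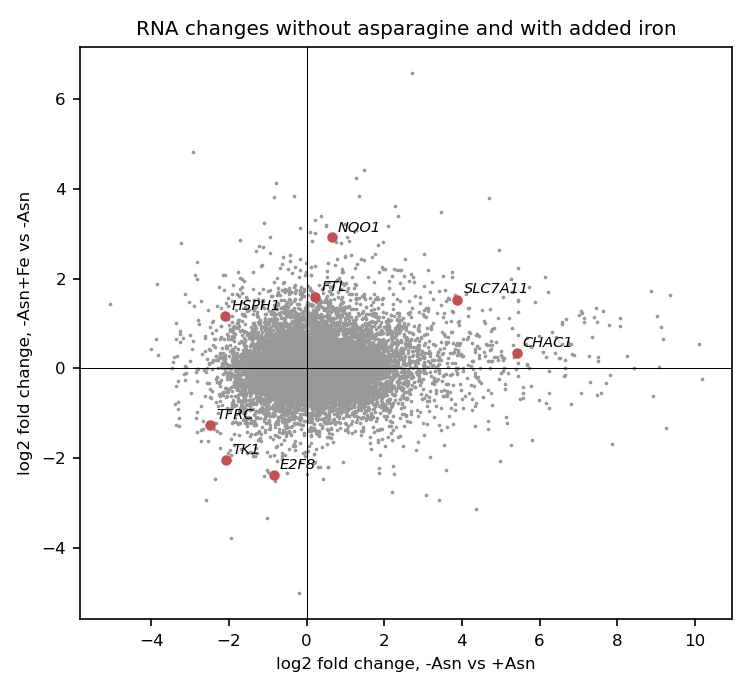
Log2 fold change of each tested gene in -Asn vs +Asn (horizontal axis) and in -Asn+Fe vs -Asn (vertical axis), with 8 genes labelled. Both axes use the same -Asn libraries, and values of genes with few counts depend on the fit. TFRC lies at -2.49 and -1.26, HSPH1 at -2.09 and 1.16, and SLC7A11 at 3.88 and 1.53.

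The iron-supplemented cells were last compared with complete medium. ATF4 and amino acid response genes were higher, 32 of 33 (median log2 1.76, camera adjusted p = 1.54e-14, and adjusted p = 0.0144 with an estimated correlation), and cholesterol genes were lower, 19 of 23 (median log2 -0.89, camera adjusted p = 8.66e-07, and adjusted p = 0.0297 with an estimated correlation). All 39 S phase genes were lower by a median log2 of -2.72, and 34 of 36 G2 and mitosis genes by -1.62 (camera adjusted p = 4.02e-23 and 8.29e-15, and adjusted p = 0.0538 for both with an estimated correlation). Of 23 p53 targets 20 were higher (camera adjusted p = 2.65e-07), and of 29 precursor B cell markers 21 were lower and 5 higher (camera adjusted p = 0.000120), and the adjusted p was 0.0538 for both with an estimated correlation. TFRC was at 44.3 CPM against 599 (log2 -3.76), FTL at 1323 against 378 (log2 1.81), and COL21A1, a collagen gene, at 1281 counts against 3 (ratio 413, interval 141 to 2005). ASXL3 was higher by log2 8.32 (7.95 to 9.01 in other settings), and GINS2 and RAD54L, of DNA replication and repair, were lower (log2 -4.24 and -4.15). ASNS was at 0.672 ± 0.230 CPM in -Asn+Fe (adjusted p = 0.0365), a call lost with DESeq2, no low-count filter or a 1.2-fold minimum, and without +Asn replicate 1, +Asn replicate 2 or -Asn+Fe replicate 3.

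Further lists differed between -Asn+Fe and +Asn. Ribosome biogenesis genes held 1 up and 30 down of 34, oxidative phosphorylation 2 up and 46 down of 58, and fatty acid synthesis 2 up and 11 down of 13 (camera adjusted p = 1.34e-07, 8.66e-07 and 0.000812, and adjusted p = 0.0958, 0.454 and 0.117 with an estimated correlation). Unfolded protein response genes held 16 up and 3 down of 23, heat shock genes 2 up and 9 down of 12, and H3K4 methyltransferase complexes 2 up and 13 down of 22 (camera adjusted p = 0.000761, 0.00958 and 0.00958, and adjusted p = 0.117, 0.368 and 0.266 with an estimated correlation). Heme and iron-sulfur cluster synthesis held 4 up and 18 down of 29, mitochondrial mRNAs 0 up and 11 down of 13, and metallothioneins 1 up and 5 down of 6 (camera adjusted p = 0.00958, 0.00219 and 0.0199, and adjusted p = 0.423, 0.423 and 0.297 with an estimated correlation). Replication-dependent histones held 17 up and 3 down of 45, mitochondrial aminoacyl-tRNA synthetases 1 up and 9 down of 15, and autophagy and lysosome 18 up and 8 down of 36 (camera adjusted p = 0.0169, 0.0169 and 0.0290, and adjusted p = 0.423, 0.258 and 0.414 with an estimated correlation). With library totals only, the histone and mitochondrial synthetase lists did not pass (0.0736 and 0.1002), nor did the autophagy list without -Asn+Fe replicate 2 (0.0572). Adjusted over the list alone, the counts in -Asn+Fe vs +Asn stayed the same except in the lists that follow, given as higher and lower: 33 and 0 for ATF4 genes, 1 and 31 for ribosome biogenesis, 11 and 7 for cytosolic and 2 and 9 for mitochondrial aminoacyl-tRNA synthetases, 13 and 6 for the JmjC list, 10 and 6 for NRF2 targets, 4 and 7 for ribosomal proteins, 17 and 2 for replication-dependent histones and 6 and 21 for precursor B cell markers. The median, mean and camera direction differed in sign for iron handling, the other dioxygenases and the fibroblast and epithelial markers here, and for the myeloid list in -Asn+Fe vs -Asn.

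The test called 11609 genes (64.7%), 5893 higher and 5716 lower, with 3098 and 1890 at least 2-fold. With library totals only the calls became 8066 higher and 3984 lower (median shift 0.25), with upper-quartile factors 7672 and 4255 (0.21), and the stricter low-count filter, which tests fewer genes, left 7647 calls (0.17).

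In H3K4me3, more peaks were called in the libraries of asparagine-starved cells. Read depth and enrichment of the ChIP libraries are not known here, and both can change the number and width of calls. The shift was uneven, with 16679 peaks in -Asn replicate 1 and 16215 in +Asn replicate 2. The -Asn libraries held 17454 ± 711 peaks and the +Asn libraries 16039.7 ± 235, covering 28.2 ± 1.88 and 25.7 ± 0.577 Mb. Over 19279 merged regions, 552 were called in all 3 -Asn libraries and in 0 of 3 +Asn libraries, and 55 the other way round. Gained regions were short, with a median width of 449 bp against 1317 bp over all regions, and 107 of them (19.4%) lay within 1 kb of the 5' end of a gene, against 10946 (56.8%) of all regions. A further 103 lay in other exonic sequence, 186 in introns and 156 between genes. ISG20, an interferon-inducible exonuclease whose RNA rose from 19.0 ± 0.627 to 99.6 ± 12.5 CPM, gained a region at its 5' end (chromosome 15, 88635582 to 88636431 of hg38), called in 0 of 3 +Asn and 3 of 3 -Asn libraries.

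The exact two-sided permutation test of the peak numbers gave p = 0.1, the smallest that 3 against 3 libraries can give. Gains and losses count calls with no test per region. Without -Asn replicate 1, the library with fewest peaks in its group, 1054 regions were gained and 58 lost. Leaving out any library loosens the rule, so the counts of gained and lost regions can only stay or rise. Among regions wider than the median, 3 were gained or lost.

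The widths of 13883 regions called in all 9 libraries were compared next. CD69, an early activation antigen, had a region at its 5' end (chromosome 12, 9758211 to 9761026) that widened from 488 ± 255 to 2476 ± 80.3 bp without asparagine. A region in an exon of MACF1 (chromosome 1, 39268044 to 39271430) widened from 584 ± 297 to 3146 ± 167 bp. Other wide gains lay in an exon of TBC1D16 at the 5' end of AC116025.2 (chromosome 17, 79991720 to 79994067, log2 2.58), in an exon of EIPR1 (chromosome 2, 3255632 to 3257955, log2 2.44) and between genes 364195 bp from PTPRC (chromosome 1, 199002652 to 199006003, log2 2.46). Regions that narrowed lay at the 5' end of CD48 (chromosome 1, 160709107 to 160712242, log2 -0.78), in an intron of MDS2 (chromosome 1, 23599284 to 23602083, log2 -0.96), and in exons of HSH2D (log2 -0.87), DGKD (log2 -0.74) and IDI1 (log2 -0.71). With outer spans in place of covered lengths the EIPR1 and HSH2D calls were lost, and the IDI1 call was lost among regions above the median width (adjusted p = 0.0563), with only the libraries compared (0.0654), and without +Asn replicate 1, +Asn replicate 2, -Asn replicate 2, -Asn replicate 3 or -Asn+Fe replicate 2.

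At promoters of the named genes, the region at SLC7A11 (chromosome 4, 138239046 to 138243103) widened from 876 ± 382 to 3754 ± 186 bp without asparagine (adjusted p = 0.000607), and that at DLX2 (chromosome 2, 172099947 to 172103852) from 995 ± 51.7 to 3605 ± 50.3 bp. TNFRSF10B went from 1046 ± 225 to 2792 ± 189.5 bp, LMO2 from 606 ± 96.7 to 1696 ± 206 bp, CHAC1 from 1378 ± 76.2 to 2803 ± 70.7 bp and WARS1 from 1897 ± 133 to 4074 ± 232 bp. Promoter regions of KDM6B (chromosome 17, 7833686 to 7840076) and KDM5B (chromosome 1, 202807237 to 202808806) widened by log2 0.60 and 0.70, and FTH1 by 0.48. HMGCS1 narrowed from 3356 ± 249 to 2136 ± 269 bp and BID from 3808 ± 74.3 to 2369 ± 198 bp, with IGLL1, SCD and TK1 also narrower (log2 -0.44, -0.44 and -0.35). Widths at TFRC, ATF4, DDIT3 and MYC gave log2 changes of -0.01, -0.02, -0.04 and 0.02 and did not pass the test. The broad regions at HOXA9 and MEIS1, targets of the KMT2A fusion, covered 26990.0 ± 63.9 and 16888 ± 426 bp in +Asn and 27156 ± 208 and 16675 ± 1111 bp in -Asn.

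Of ATF4 and amino acid response genes with such a promoter region, 16 of 27 widened and 1 narrowed, and of p53 targets 12 of 21 widened (camera adjusted p = 0.000243 and 0.000736, and adjusted p = 0.657 and 0.770 with an estimated correlation). Relative to other regions, promoters of cytosolic ribosomal proteins were narrower, with 7 of 73 narrower and 1 wider, although 33 of these genes rose in RNA and 5 fell (camera adjusted p = 9.73e-09, and adjusted p = 0.657 with an estimated correlation). Of cholesterol genes 5 of 22 narrowed, of S phase genes 1 of 36, of heat shock genes 2 of 12 and of ribosome biogenesis genes 0 of 33, where 1 widened (camera adjusted p = 2.17e-07, 7.43e-06, 0.000382 and 0.000736, and adjusted p = 0.657 for each with an estimated correlation). Their median log2 width changes were small, at -0.074, -0.025, -0.038 and -0.012. The median over all 13883 regions was 0.086, so the camera direction down is relative to a general widening. Of fatty acid synthesis genes 2 of 12 narrowed and 1 widened, and of precursor B cell markers 1 of 21 narrowed (camera direction down, median log2 -0.043 and -0.042, camera adjusted p = 0.0145 and 0.00231, and adjusted p = 0.848 for both with an estimated correlation). With each library centred on its median width, and so relative to it, the narrower promoters numbered 22 of ribosomal proteins, 14 of cholesterol, 10 of S phase, 9 of ribosome biogenesis, 7 of precursor B, 6 of fatty acid and 5 of heat shock genes. The wider promoters then numbered 13 of ATF4 and 10 of p53 genes. CNTN4, JMY, GDF15, ESRP1 and GDAP1L1, whose RNA rose from almost 0, had 0 regions within 1 kb of the outer 5' end of the gene. The same held for other named genes, among them TRIB3 and CDKN1A, which were well expressed in -Asn. A promoter farther inside a gene is missed by this window, so whether these genes carried the mark stays unknown.

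In all, limma called 2241 of the 13883 regions, 2043 wider and 198 narrower, in a test of log2 width chosen after the peak table was seen to hold positions alone. With each library centred on its median width the calls were 1203 wider and 1024 narrower of 2227, and without +Asn replicate 3, -Asn replicate 2 or -Asn replicate 3 the count of calls became 1236, 1160 and 1204.

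Few H3K4me3 regions differed between starved cells with and without iron. The -Asn+Fe libraries held 17530.3 ± 549 peaks, against 17454 ± 711 in -Asn (exact permutation p = 0.9). Between -Asn+Fe and -Asn, 47 regions were gained and 52 lost. Of the 552 regions gained without asparagine, 313 (56.7%) were called in all 3 -Asn+Fe libraries and 37 (6.70%) in 0, and of the 55 lost regions 29 were called in 0 and 5 in all 3. Promoter widths in -Asn+Fe were 3909.7 ± 35.4 bp at SLC7A11, 3467 ± 287 bp at DLX2, 2871 ± 173 bp at CHAC1 and 5806 ± 245 bp at KDM6B. FTL, whose RNA rose with iron, went from 2662 ± 507 to 3043 ± 181 bp, and HMOX1 had a region called in 0, 1 and 2 libraries of +Asn, -Asn and -Asn+Fe.

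The limma test of widths called 0 of 13883 regions between -Asn+Fe and -Asn, with 1046 at an unadjusted p under 0.05 against 694 by chance (1412 after centring), and 1 region passed without -Asn+Fe replicate 1. Camera called the promoter widths of the ATF4, NRF2 and ribosomal protein lists up (adjusted p = 0.0237, 0.0237 and 0.0283) and of the S phase and G2 lists down (0.0237 for both), and adjusted p = 0.998 for each with an estimated correlation. Gained and lost regions together numbered 99, fewer than the 119 that another split of the same 6 libraries gave. They numbered 241, 226 and 163 without -Asn replicate 1, 2 and 3, and 200, 217 and 187 without -Asn+Fe replicate 1, 2 and 3. The looser rule with a library left out can only keep or raise these counts.

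Against complete medium, iron-supplemented starved cells gained 617 regions and lost 49, and the MACF1, AC116025.2, CD69 and EIPR1 regions were again wider (log2 2.52, 2.47, 2.42 and 2.31). A region in an intron of the noncoding gene AL589693.1 (chromosome 6, 156201943 to 156206130) was wider by log2 2.43. The MDS2 region narrowed (log2 -1.49), as did regions in exons of MAGI1, LYSMD4 and ALDH1A2 and in an intron of LGR6 (log2 -1.39, -1.21, -1.17 and -1.17). Of the regions gained against +Asn, 313 were shared by -Asn and -Asn+Fe, and 1230 regions were wider and 117 narrower in both. Independent lists would share 17.7 gained, 237 wider and 3.64 narrower regions. Both comparisons use the same +Asn libraries, so part of that excess can come from them. In 20 simulated sets of widths with no effect and the same shared libraries, 0 regions were called in the same direction in both, against 1347 here. At most 1 region per set was called in -Asn vs +Asn, so these sets cannot gauge the part that comes from the +Asn libraries. Gained regions were not simulated. Limma called 1865 regions, 1610 wider and 255 narrower (1241 and 1050 after centring), and the count became 1050, 945 and 1095 without +Asn replicate 3, -Asn+Fe replicate 1 and -Asn+Fe replicate 3. Without -Asn+Fe replicate 2 the gained and lost regions numbered 1039, a count that leaving out a library can only keep or raise. The LYSMD4 call was lost with any single +Asn library, -Asn+Fe replicate 2 or -Asn+Fe replicate 3 left out, and among regions above the median width (adjusted p = 0.0567). With outer spans the EIPR1, LYSMD4 and ALDH1A2 calls were lost (adjusted p = 0.0834, 0.125 and 0.143).

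By promoter width in -Asn+Fe vs +Asn, ATF4 genes held 15 wider and 1 narrower of 27, and p53 targets 11 wider of 21 (camera adjusted p = 2.61e-06 and 0.000218, and adjusted p = 0.701 and 0.738 with an estimated correlation). S phase genes held 6 narrower of 36 and cholesterol genes 4 narrower and 1 wider of 22 (camera adjusted p = 8.80e-10 and 3.86e-06, and adjusted p = 0.701 for both with an estimated correlation). Ribosomal proteins held 3 narrower and 1 wider of 73 and precursor B cell markers 2 narrower and 1 wider of 21 (camera adjusted p = 5.68e-05 and 0.0348, and adjusted p = 0.801 for both with an estimated correlation). Ribosome biogenesis genes held 1 narrower and 1 wider of 33 and heat shock genes 1 narrower of 12 (camera adjusted p = 0.00434 and 0.0147, and adjusted p = 0.738 for both with an estimated correlation). After centring, 16 S phase, 14 ribosomal protein, 12 cholesterol, 8 ribosome biogenesis, 5 precursor B and 4 heat shock promoters were narrower, and 13 ATF4 and 11 p53 promoters wider. The precursor B list had a median above 0 (log2 0.03) and a camera direction down. The direction was also down for the S phase, cholesterol, ribosomal protein, ribosome biogenesis and heat shock lists. Their median log2 width changes were -0.072, -0.108, -0.023, -0.0099 and -0.0037, against 0.067 over all 13883 regions.

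**Figure D4:**
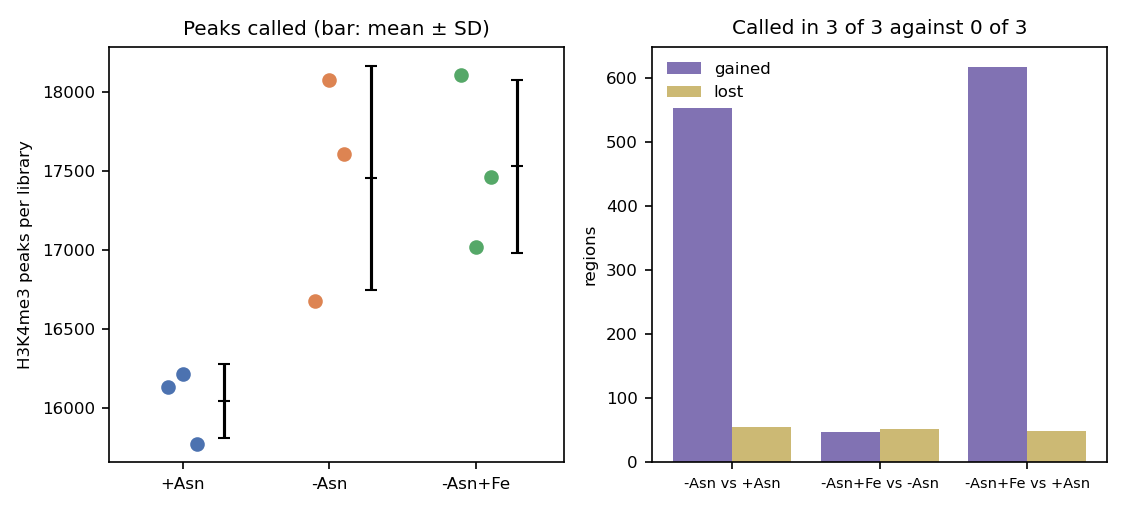
Left: H3K4me3 peaks per library (points, with the mean and SD of 3 libraries beside them; the axis does not start at 0). Right: merged regions called in all 3 libraries of the first group and 0 of 3 of the second (gained), or the reverse (lost), for each comparison. The bars show 552 gained and 55 lost in -Asn vs +Asn, 47 and 52 in -Asn+Fe vs -Asn, and 617 and 49 in -Asn+Fe vs +Asn.

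Genes whose promoter region widened tended to have more RNA. Of 1437 genes with a wider region at the 5' end in -Asn vs +Asn, 904 (62.9%) rose in RNA and 194 fell, where 31.6% of all 11926 genes compared rose (Fisher's exact test, odds ratio 4.52, adjusted p = 2.06e-150). Of 187 genes with a narrower region 128 (68.4%) fell in RNA, where 36.9% of all genes fell (odds ratio 3.79, adjusted p = 1.70e-18). SLC7A11, DLX2, TNFRSF10B, WARS1 and CHAC1 were among the former and HMGCS1, BID and IGLL1 among the latter. After centring each library on its median width, fewer promoters were wider than narrower: 510 of 725 genes with a wider region (70.3%) rose in RNA and 707 of 1147 with a narrower region (61.6%) fell. The 65 genes that gained a promoter region in -Asn had a median RNA log2 fold change of 1.36, with 44 higher and 8 lower, against 0.44 in 154 genes whose region was called in part of both groups (permutation p = 0.0002). In -Asn+Fe vs +Asn, 764 of 1127 genes with a wider region (67.8%) rose in RNA (odds ratio 5.75, adjusted p = 2.31e-160), and 564 of 780 (72.3%) after centring.

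Across genes, which are not independent replicates, the width and RNA log2 fold changes correlated at r = 0.420 (rho = 0.384) in -Asn vs +Asn, 0.112 (0.114) in -Asn+Fe vs -Asn and 0.446 (0.409) in -Asn+Fe vs +Asn. Each of these 3 relations had a permutation p and an adjusted p of 1e-05, the smallest that 100000 resamples can give.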

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

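The width tests and their settings, and the setting that drops peaks under 500 bp, were chosen after the data were seen. Of the values of 450 single-gene results in other settings, 4337 of 4481 kept direction and side of the threshold, 94 became weaker, 49 stronger and 1 reversed: GCLM in -Asn vs +Asn was at 0.0102 with library size only (adjusted p = 0.927) against -0.20 (adjusted p = 0.0479). Of the weaker values 43 came from glmTreat, by its stricter construction. Leaving out 1 library kept 3921 of 4050. Of list values 151 of 200 held, 44 of the losses came with an estimated correlation, and 444 of 450 held without 1 library. Of region values 81 of 90, and 170 of 180 without 1 library, held.

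RNA calls in -Asn+Fe vs -Asn fell to 2323 with glmTreat, by construction, and those in -Asn+Fe vs +Asn to 7647 with the stricter low-count filter, which tests fewer genes. Lists called became 2 in each comparison with an estimated correlation, and 30 in -Asn vs +Asn and 31 in -Asn+Fe vs +Asn with fry, which tests each list alone. Among regions wider than the median, gained and lost regions numbered 3, 0 and 3, by construction since gained regions were short. Without peaks under 500 bp they numbered 58 in -Asn+Fe vs -Asn and 439 in -Asn+Fe vs +Asn. Width calls above the median width, where fewer regions are tested, were 1017 and 895.

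Without 1 library, RNA calls ranged from 10038 to 11282, 4038 to 5418 and 10831 to 12523, opposite changes with iron from 1309 to 1952 and changes in the same direction from 1564 to 2273. Lists called ranged from 14 to 15, 16 to 19 and 17 to 19. Gained and lost regions ranged from 607 to 1112, 99 to 241 and 666 to 1039, the highest without -Asn replicate 1, -Asn replicate 1 and -Asn+Fe replicate 2. Of the regions changed without asparagine, 42 returned with iron (37 gained, 5 lost), and 43 to 151 without 1 library: 151, 67 and 77 without -Asn replicate 1, 2 and 3, and 87 and 68 without -Asn+Fe replicate 1 and 3. Leaving out a library loosens the rules for gained, lost and returned regions, so these counts can only stay or rise, by construction. Widths called ranged from 1160 to 2696, 0 to 1 and 945 to 2167, and the promoter correlation from 0.408 to 0.421, 0.0952 to 0.117 and 0.434 to 0.446. The cause of the other ranges, and of the uneven rises between libraries, was not tested.

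With the replicate number as a block (replicate block), RNA calls were 10769, 5155 and 11380 and width calls 1606, 0 and 1346. Libraries with the same number were no closer than others (r from -0.0806 to 0.0721 in RNA against -0.0864 to 0.0983, and from -0.211 to 0.0933 in widths against -0.141 to 0.226). Of the named calls, FTL and GCLM in -Asn vs +Asn, LMO2 and LARS2 in -Asn+Fe vs -Asn and the LYSMD4 region in -Asn+Fe vs +Asn did not pass in this fit (adjusted p = 0.0552, 0.0663, 0.0511, 0.0738 and 0.0689). For gained and lost counts alone, which come from no test, no blocked value can be given. Count-based settings for peaks (DESeq2, RLE, column or library totals, no filter, score threshold, pseudocount, 2 groups only) and the column total for the return and the promoter relation were not run, since the table has no counts. Thinned to the smallest library, RNA calls were 10547, 5350 and 11203. Most of the smallest planted changes were missed in simulated data, in which depth was not varied.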

Other observations

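The split counts, the test of hinokitiol, of leaving out each of the 6 libraries and of a library-wide width shift, of scaling for TFRC and FTH1 and of less growth, the interval over libraries and the genes described first here were chosen only after the results were seen. Some genes with at most 3 counts over the +Asn libraries reached 1 CPM in -Asn: 25 genes, of which 14 are protein coding and 5 had an H3K4me3 region within 1 kb of the outer 5' end. A promoter farther inside a gene is missed by that window. With iron 10 were higher still and 2 lower. They include CNTN4, JMY, GDF15 and COL21A1, the noncoding LINC00632 at 4.03 CPM in -Asn and 9.18 in -Asn+Fe, DSC1, of cell adhesion, at 2.16 and 6.82, and FCER1G, an immune receptor chain, at 1.13 and 1.04.

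Replication-dependent histone genes went against the cell-cycle genes, with 19 up and 1 down of 45 in -Asn vs +Asn (camera adjusted p = 0.00380, and adjusted p = 0.396 with an estimated correlation). H2AC6 rose from 3.03 ± 0.313 to 21.99 ± 1.41 CPM and H2BC12 from 8.80 ± 0.563 to 28.9 ± 3.39 CPM. These levels were low in +Asn and the RNA selection is not described here, so the counts may not stand for all histone mRNA. T and NK markers held 6 up and 0 down of 8 (camera adjusted p = 0.102), with GATA3 at 6.91 ± 1.72 and 16.02 ± 1.82 CPM. Myeloid markers held 6 up and 2 down of 10 (0.239), with SPI1 at 51.6 ± 2.68 and 81.1 ± 8.85 CPM. Fibroblast and epithelial markers held 3 up and 3 down of 6 (0.810), with ACTA2 at 1.46 ± 0.240 and 9.64 ± 2.38 CPM, and the erythroid list had 1 tested gene and no test.

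Cell-cycle genes fell with iron: the 75 S phase and G2 genes had a median log2 change of -0.98 in -Asn+Fe vs -Asn, and the libraries' medians over these genes differed by -0.98 with a 95% interval over libraries from -1.08 to -0.87, though 4 of the 36 G2 genes had risen without asparagine. The S phase list did not pass with an estimated correlation (adjusted p = 0.0545), and the G2 list did (0.0182). The tables argue against smaller depth (median -0.99 with all libraries thinned), against the composition scaling (-0.93 with library totals only) and against 1 library (-0.99 without the smallest, -Asn+Fe replicate 2, and -0.96 at the highest without each of the 6 in turn). The upper end of the interval over libraries was -0.84 at the highest in these settings. Hinokitiol in place of iron stays open, since the labels name 0 libraries with hinokitiol and no ferric nitrate. Iron overload slowing the cycle is one candidate explanation that the design cannot separate from hinokitiol.

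More H3K4me3 regions were gained than lost without asparagine. For the 65 genes with a gained promoter region, RNA argues against more sensitive calling as the whole cause. Their median log2 change lay 0.92 above that of genes with partly called regions (permutation p = 0.0002). These gene sets were not matched for RNA level in +Asn, which limits this reading. The gained regions in other exonic sequence, in introns and between genes (103, 186 and 156) were not covered, so for them it stays open. A library-wide shift of width stays open: after centring, 54.0% of called regions were wider, but centring itself pulls the share toward an even split. A wider mark at genes with more RNA may reflect their transcription, which was not tested.

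TFRC fell and FTH1 rose without asparagine, while the iron handling list as a whole did not pass (camera adjusted p = 0.217). Scaling is argued against: the highest TFRC change over the other scalings was -2.29 and the lowest FTH1 change 1.18. A shift of counts from FTH1 pseudogenes to FTH1 is argued against: the pseudogenes held 3.67 CPM in +Asn and 7.19 in -Asn. FTH1 and its pseudogenes summed rose by 1.21 (SE 0.149), a sum that is almost all FTH1. Shared reads that were left out of the counts would be in neither, so their part stays open. Less growth in place of an iron response stays open: with iron TFRC fell again (log2 -1.26) and so did the S phase genes, but both explanations predict that fall, so it does not tell them apart, and no other value here does.

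Each comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05. Every split other than the real one holds both media in each group. Real differences between media then widen the spread within groups, so few calls there say little about chance. Fitted on the 6 libraries compared, RNA calls were 10571, 4662 and 11980 in the real splits (1 of 10 splits with as many calls, in each), and the highest other was 0. Width calls were 1776, 0 and 1910, and the highest other 0, 8 and 0. As many calls were seen in 1, 10 and 1 of the splits. Gained and lost regions together numbered 607, 99 and 666, and the highest other 64, 119 and 51.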
